A study of Mus musculus with 6 samples.

How the data were processed

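RNA from the hearts of wild-type mice was sequenced in 6 libraries: 3 came from hearts that had received an adeno-associated virus carrying an adenine base editor and a guide against Camk2d (edited), and 3 from untreated hearts (control). The labels name heart tissue, total RNA, fragmentation, reverse transcription, second-strand synthesis, adapter ligation and PCR. They give no strand information, age, sex, dose, interval or part of the heart. They do not state in words that each replicate is a separate animal, so the p-values measure the spread between these samples. The virus, the editor and the edit were all absent from the controls, so they share 1 contrast. Any difference between the groups in collection, preparation or sequencing would share it too.

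The authors deposited 1 table of read counts per gene, raw and not normalized, for 35976 genes named by symbol. Per the submitters' processing notes, FastQC, cutadapt, STAR and featureCounts were used with the mouse build mm10; their versions and settings are not given in the sources used here. The deposited counts came in 2 columns per library, named after the mates of a read pair, and 0 genes differed between them in any library. Each pair was therefore counted as 1 library. Total counts per library ranged from 17062412 to 23097998. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom, over genes with at least 20 counts, ranged from 3.95 to 14.41.

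How reads that match several places were treated is not stated, and this affects genes with near-identical copies, among them processed pseudogenes and mitochondrially encoded genes with nuclear copies. Reads that overlap 2 genes are a further source of uncertainty. Of the genes named in the text, 15 share exon bases with another gene in the authors' annotation, most by a few percent. Art1 shares 24.9% of its exon bases with Chrna10 on the opposite strand, and Mybpc2 shares 39.0% with Fam71e1. Of the exon boundaries in the deposited table, 88.4% are also in GENCODE M21, which is on the same build and was used for gene types and for the exons of Camk2d.

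From these counts, genes were kept by edgeR's filterByExpr with the groups, which left 14879. Libraries were scaled by TMM factors, which lay between 0.971 and 1.039. Groups were compared with edgeR's quasi-likelihood test (version 4.0.16, robust, in R 4.3.3) with group as the only term, adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold for an adjusted p. A second test asked whether a change exceeded 1.5-fold (glmTreat on the same fit). Fold changes are log2, edited over control, with their standard errors (SE), and levels are TMM-normalized CPM (counts scaled to a library total of 1e+06) unless called unscaled. For Camk2d alone, a two-sided exact permutation test of log2 CPM over the 20 arrangements of 6 libraries was run. With 3 libraries against 3 its smallest possible p is 0.1.

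Before the data were examined, 37 gene lists were fixed: programs of heart muscle, metabolism, stress and immunity, markers of cell types and tissues a heart sample can hold, and signs of handling and sex. The 33 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 (limma 3.58.1), again with a correlation estimated for each list, and with fry, which asks whether a list's genes moved, on balance, one way. For each list the members past the threshold were counted among all tested genes and adjusted over the list alone. The named genes follow a rule fixed at the same time: the 4 Camk2 genes; the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups and at least 1 CPM in a group, leaving out predicted genes (Gm and Rik symbols), marked pseudogenes and names that are only identifiers; up to 4 members of each list with the smallest p; and the 5 genes with the smallest adjusted p. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule picks are not reported here.

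The same steps were tested on simulated counts drawn from the real means and library sizes, with 200 of 14879 genes changed. For the comparison of edited with control, 71.6% of genes changed 1.5-fold were called, 77.6% of those changed 2-fold and 92.4% of those changed 4-fold. Of 14679 unchanged genes, 15 were called, beside 161 of the 200 changed genes. Each simulated gene varied on its own, without differences of tissue or sex that many genes of a heart share. These rates therefore need not hold for the real calls.

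Alternatives were DESeq2's size factors, upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2's Wald test (version 1.42.0), limma voom with quality weights, the replicate number as a block, leaving out each library, leaving out mitochondrially encoded and haemoglobin genes, and other thresholds. Alternatives added after the data were seen left out controls 1 and 3 (so that control 2 was the only control and the spread came from the edited hearts alone), took the CPM of the atrial transcript Myl7 as a covariate, removed the trend of counts with gene length in each library, or left out pseudogenes and mitochondrially encoded genes. Sequences of mitochondrial genes and processed pseudogenes were matched to GENCODE M21 transcripts with blastn 2.17.0. Splicing, editing at the target base and off-target editing were not analysed here, since a table of counts per gene does not hold them.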

Results

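The series measured RNA in mouse hearts after base editing aimed at the donor site that opens intron 7 of Camk2d. Camk2d encodes the main cardiac isoform of calcium/calmodulin-dependent protein kinase II (CaMKII), a kinase that phosphorylates calcium-handling proteins. The edited hearts carried an adeno-associated virus with TadA8e, an evolved adenine deaminase that makes A-to-G changes, joined to a Cas9 named Sauri, under a MYL2 promoter active in heart muscle, together with a guide RNA called sgRNA7. The control hearts were untreated. Each group held 3 libraries. Total counts were 17062412, 19515624 and 19743748 in controls 1, 2 and 3, and 23097998, 17349520 and 17265842 in edited 1, 2 and 3. Mitochondrially encoded genes took 12.04% to 13.87% of counts.

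Camk2d RNA was lower in every edited heart. Its level was 223 ± 3.5 CPM in controls (SD, n = 3) and 144 ± 17.7 CPM in edited hearts (SD, n = 3), with single libraries at 226, 220 and 224 CPM against 138, 130 and 164 CPM. This left 64.4% of the control level, with a range of 58.1% to 71.4% at ±2 SE. The log2 change was -0.64 (SE 0.08), with an adjusted p of 4.76e-04 in edgeR's quasi-likelihood test. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Camk2d did not pass the test for a change above 1.5-fold (adjusted p = 1). With controls 1 and 3 left out, an alternative added after the data were seen in which control 2 is the only control and the edited hearts alone give the spread, the log2 change was -0.60 and the adjusted p 0.0569, in a range of 3.13e-19 to 0.0569 over the alternatives.

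In mm10, Camk2d lies on chromosome 3 from 126596354 to 126846326 on the plus strand. Counting exons from the first, all 9 coding GENCODE M21 transcripts with enough exons share intron 7, from 126780463 to 126783954 (3492 bp). The targeted splice site is at its start, next to exon 7 (126780360 to 126780462, 103 bp). The counts cover the whole gene, so they show the amount of Camk2d RNA and not how it was spliced. The other CaMKII genes did not pass the threshold. Camk2a was at 79.9 ± 6.2 CPM in controls and 79.0 ± 7.8 in edited hearts, Camk2b at 18 ± 3.9 and 19.3 ± 3.3, and Camk2g at 76.8 ± 2.9 and 80.2 ± 1.2 (SD, n = 3). Camk2d made up 56.1 ± 0.2% of the summed CPM of the 4 Camk2 genes in controls and 44.6 ± 3.8% in edited hearts (SD, n = 3). In the list of 13 CaMKII and calmodulin genes, Camk2d was the gene past the threshold, and the list did not pass its set test (adjusted p = 0.922).

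**Figure D1:**
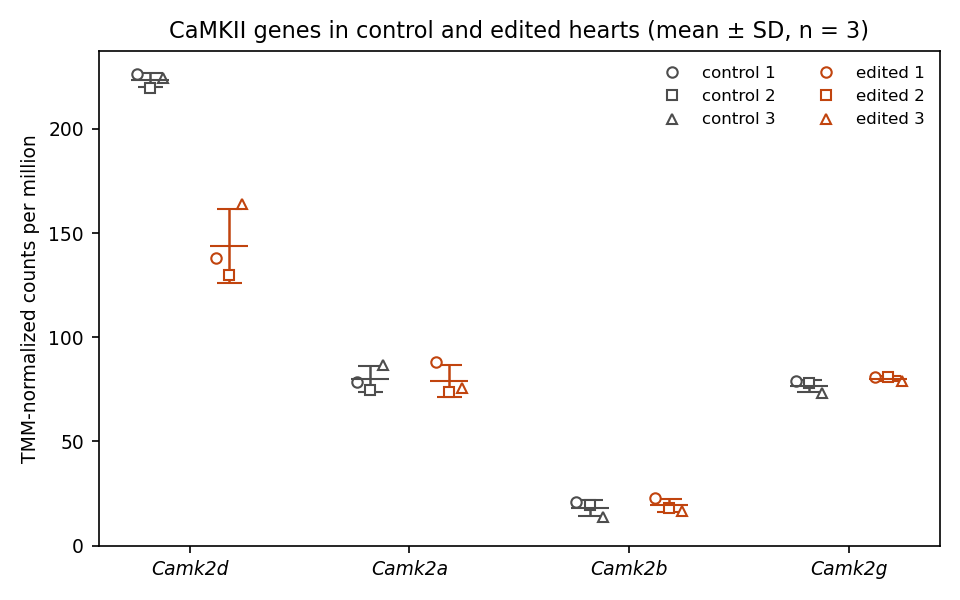
TMM-normalized CPM of the 4 Camk2 genes. Each symbol is 1 library, horizontal lines are group means and bars are the SD of 3 libraries. Camk2d lies between 220 and 226 CPM in controls and between 130 and 164 CPM in edited hearts, while the groups of Camk2a and Camk2b overlap.

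Beyond Camk2d, many genes shifted, most of them by small amounts. Of 14879 tested genes, 733 were higher and 705 lower in edited hearts, 1438 in all, with a median absolute log2 change of 0.40 among them. An absolute log2 change of 1 or more was estimated for 221 of these genes. A change above 1.5-fold was called for 43 genes, of which 29 were higher and 14 lower. Groups did not overlap for 29.3% of tested genes, against 10% by chance. With upper-quartile scaling the calls were 849 higher and 531 lower. The number of calls rested on single libraries: it was 850 without control 1, 446 without control 3 and 728 without edited 3, and for changes above 1.5-fold 18 without control 1, 68 without control 2, 20 without control 3, 70 without edited 2 and 26 without edited 3. With Myl7 as a covariate, an alternative added after the data were seen, the number of calls fell to 121, and the calls above 1.5-fold to 11. Controls 1 and 3 hold little of the atrial transcripts Myl7, Nppa and Myl4, and a fit without them has 1 control library.

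The genes with the smallest adjusted p were Art1, an ADP-ribosyltransferase (42.6 ± 1.6 to 17.4 ± 1.0 CPM), Cacnb2, a subunit of the L-type calcium channel (142 ± 4.2 to 85.2 ± 3.2), Tmem100 (41.9 ± 2.2 to 20.6 ± 1.8), Rpl3l, a ribosomal protein specific to striated muscle (39.2 ± 3.1 to 21.4 ± 0.06), and Bex4, which rose (1.51 ± 0.17 to 6.30 ± 0.24; control to edited, SD, n = 3). Their adjusted p ran from 6.6e-07 for Art1 to 2.71e-05 for Rpl3l. The largest rises were all in genes scarce in control hearts. Clca3a2 rose from 0.27 ± 0.33 to 4.65 ± 0.56 CPM. Tub rose from 0.57 ± 0.09 to 4.71 ± 1.4, and the potassium channel gene Kcnma1 from 0.13 ± 0.03 to 1.55 ± 0.43. Myh8, a perinatal myosin, reached 6.68 ± 2.6 CPM, Frmpd1 3.73 ± 1.7, Rprm 1.71 ± 0.66, Clic6 1.47 ± 0.81, Slc6a7 1.46 ± 0.54 and Uts2b 1.09 ± 0.56, each from below 0.6 CPM. Among the largest falls were Drd2, a dopamine receptor (7.12 ± 0.62 to 1.90 ± 0.54 CPM), Cntn2, a cell adhesion protein (16.7 ± 2.6 to 5.56 ± 1.2), the nuclear receptor Nr4a3 (39.6 ± 9.5 to 11.9 ± 3.5) and the stress factor Atf3 (21.9 ± 4.1 to 8.57 ± 2.2). Pcp4, Ankrd63 and Mir692-3 fell from at most 2.82 CPM. The other 3 were ATP6, COX3 and COX2 of the mitochondrial genome, which have near-identical nuclear copies. Some of these calls were lost without 1 library: Myh8 without control 1, control 3 or edited 1 (adjusted p 0.0586, 0.124 and 0.0869) and without a filter (0.0634), Frmpd1 without control 1 (0.0505), Nr4a3 without control 1, control 3, edited 1 or edited 2 (0.102, 0.052, 0.0847 and 0.117), Atf3 without control 1 or edited 3 (0.052 and 0.0632), ATP6 without control 3 or edited 2 (0.0693 and 0.0689), and COX3 and COX2 without edited 2 (0.0606 and 0.0536), all by edgeR. With Myl7 as a covariate, added after the data were seen, 48 of 88 named genes lost their call. In that setting 36 kept their result, called or uncalled.

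Some genes of calcium handling, contraction and excitation were lower in edited hearts. Of 26 calcium-handling genes, 9 fell and 0 rose (2 higher and 12 lower adjusted over the list alone). They included Cacnb2, Pln, the inhibitor of the sarcoplasmic reticulum calcium pump (4791 ± 151 to 3561 ± 234 CPM), Hrc, a calcium-binding protein of that compartment (544 ± 21.5 to 401 ± 17.5), and Cacna1g, a T-type calcium channel (152 ± 7.3 to 113 ± 4.9; SD, n = 3). Of 25 sarcomere genes, 10 fell and 0 rose (13 lower adjusted over the list alone), led by Tpm1 (log2 -0.56, SE 0.05), Myoz2 (-0.44, SE 0.06), Tcap (-0.42, SE 0.06) and the cardiac troponin Tnnt2 (-0.36, SE 0.05). Of 23 ion channel and gap junction genes, 5 fell and 0 rose (6 lower adjusted over the list alone), among them the potassium channel gene Kcnd2 (log2 -1.27, SE 0.15). All 3 lists passed camera with the preset correlation (adjusted p 1.72e-05, 9.9e-07 and 0.0272). With an estimated correlation none did, at adjusted p = 0.204, adjusted p = 0.167 and adjusted p = 0.475. With Myl7 as a covariate, 4 of the 9 calcium-handling, 1 of the 10 sarcomere and 0 of the 5 ion channel calls remained in edgeR, and with controls 1 and 3 left out 6, 1 and 2, while the 3 list medians were -0.16, -0.17 and -0.17, then -0.11, -0.11 and -0.11. All 3 lists passed camera with the covariate, and the other setting has 1 control library, so its list tests rest on the spread of the edited hearts alone. Without control 3, 6 sarcomere and 2 ion channel genes were called, and without control 1, 3 ion channel genes. The ion channel list lost its call with voom (adjusted p 0.223) and without control 2 (0.176), edited 1 (0.0882) or edited 2 (0.0813).

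Many genes of oxidative phosphorylation and fatty acid oxidation were also lower. Among 64 nuclear-encoded genes of oxidative phosphorylation, 34 fell and 0 rose (59 lower adjusted over the list alone), with a median log2 of -0.21. Uqcrfs1, a subunit of complex III, had a log2 change of -0.28 (SE 0.05). Of 35 genes of fatty acid oxidation, 18 fell and 1 rose (21 lower and 3 higher adjusted over the list alone), including Plin5, a lipid droplet protein (log2 -0.42, SE 0.07), and the enzymes Hadh (-0.30, SE 0.05), Decr1 (-0.29, SE 0.05) and Acadm (-0.27, SE 0.05). Camera's adjusted p was 1.25e-15 and 2.26e-05 for these lists, and with an estimated correlation adjusted p = 0.454 and adjusted p = 0.344. The number of calls in these lists depended on single libraries. For oxidative phosphorylation it was 5 without control 1, 53 without control 2, 1 without control 3 and 12 without edited 3, and 22 with upper-quartile scaling and 58 with voom. For fatty acid oxidation 10 genes fell without control 1, 5 without control 3, 8 without edited 3 and 10 with upper-quartile scaling. With Myl7 as a covariate edgeR gave 0 calls in each list, with medians of -0.12 and -0.15 and camera's adjusted p at 7.44e-05 and 0.00627. With controls 1 and 3 left out it also gave 0 calls in each, with medians of -0.11 and -0.11 (adjusted p 8.58e-06 and 0.00349, from 1 control library). Ppargc1a, a coactivator of mitochondrial genes, fell from 186 ± 19.4 to 106 ± 3.4 CPM (SD, n = 3). It belongs to a list of 15 MEF2 and class IIa HDAC targets in which Nr4a3 fell too and Adamts2 rose (2 lower and 1 higher, and 4 lower and 1 higher adjusted over the list alone; camera adjusted p 0.0272, with an estimated correlation adjusted p = 0.475). That list was not past the threshold without edited 1 or edited 2 (adjusted p 0.0871 and 0.350), with voom (0.185) or with controls 1 and 3 left out (0.131). The call of Adamts2 was lost without control 1 (0.0785), control 3 (0.0865), edited 2 (0.0538) or edited 3 (0.0555), and that of Nr4a3 without control 1 (0.102), control 3 (0.052), edited 1 (0.0847) or edited 2 (0.117). Of 29 genes of glycolysis and glucose use, 7 fell, including the glycogen phosphorylase Pygm (log2 -0.29, SE 0.05), and 1 rose, the glucose transporter Slc2a1 (0.64, SE 0.12). This list did not pass (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0941, and adjusted p = 0.700 with an estimated correlation), but did without control 2 (adjusted p 0.00587), without a filter (0.0214) and with voom (0.00209). Its falls were 4 without control 1, 2 without control 3, 2 without edited 3 and 11 with voom. Of the 13 mitochondrially encoded genes 6 fell and 0 rose (10 lower adjusted over the list alone; camera adjusted p 4.87e-15, with an estimated correlation adjusted p = 0.204), unevenly; 2 passed with controls 1 and 3 left out and 0 with Myl7 as a covariate, and 3 without control 3, 11 without edited 1 and 2 without edited 2. ATP6 had a log2 change of -1.59 (SE 0.20), while COX1 had -0.12 (SE 0.06) and was not past the threshold. In controls ATP6, COX3 and COX2 held 589, 604 and 671 CPM, against 59827 for COX1. As reads shared with nuclear copies may be missing from these counts, their falls need not be falls of mitochondrial RNA. The 6 genes covered over 50% by such a copy had a median log2 of -1.34, and the other 7 had -0.17.

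Some genes of growth and matrix and most cell cycle genes of the list were higher. Of 18 hypertrophy and fetal genes, 5 rose and 0 fell (10 higher adjusted over the list alone), among them Fhl1 (138 ± 1.0 to 197 ± 12.8 CPM), the fetal troponin Tnni1 (265 ± 38.7 to 437 ± 15.6) and Xirp2 (117 ± 6.1 to 149 ± 11.7). The list also holds Nppa and Myl4, which are atrial markers, and neither was past the threshold. Of 35 genes of extracellular matrix and fibrosis, 9 rose and 0 fell (9 adjusted over the list alone), including the matrix protein Fbln2 (188 ± 4.4 to 264 ± 13.5), Ctgf (56.5 ± 6.1 to 79.7 ± 8.1) and Cthrc1 (9.55 ± 2.2 to 15.7 ± 0.69). The elastin gene Eln, also on this list, was highest in edited 2 and not past the threshold (adjusted p 0.0975), and 8 of 10 mesothelial markers rose in the same hearts. Among 25 cell cycle genes, 17 rose and 0 fell (23 adjusted over the list alone), such as Top2a (61.2 ± 7.1 to 82.8 ± 3.3), Ccna2 (32.9 ± 3.2 to 44.0 ± 1.5) and Mcm3 (33.3 ± 3.3 to 43.6 ± 1.1). Of 19 genes of the p53 and DNA damage response, 4 rose and 0 fell (7 adjusted over the list alone): Cdkn1a, a cyclin-dependent kinase inhibitor (35.4 ± 2.6 to 50.3 ± 2.8), Ddit4l (1.90 ± 0.49 to 10.2 ± 3.3), Phlda3 (29.8 ± 1.0 to 41.1 ± 3.7) and Zmat3 (18.9 ± 1.8 to 23.7 ± 1.4; SD, n = 3). Camera's adjusted p was 3.34e-08, 6.03e-08, 1.02e-16 and 3.97e-04 in this order, and with an estimated correlation adjusted p = 0.105, adjusted p = 0.454, adjusted p = 0.291 and adjusted p = 0.167. Zmat3 lost its call without control 1 (adjusted p 0.0677), control 2 (0.0875), edited 1 (0.0652) or edited 3 (0.0749). Without control 3, 3 hypertrophy, 3 matrix and 4 cell cycle genes were called, without control 1, 3 matrix genes, and without edited 3, 11 cell cycle genes. With controls 1 and 3 left out, 2, 2, 7 and 1 members of the 4 lists passed, with medians of 0.43, 0.13, 0.48 and 0.24, and with Myl7 as a covariate 1, 1, 0 and 3, with medians of 0.31, 0.24, 0.40 and 0.21, against 0.45, 0.26, 0.40 and 0.18 with all libraries and no covariate. All 4 lists passed camera with the covariate, and the other setting has 1 control library. The matrix median was 0.13 without edited 2, and the p53 median 0.11 without control 2.

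Few immune genes passed, and stress genes went both ways. In the interferon response, 1 of 29 genes passed, Ifit2 (13.9 ± 0.94 to 17.8 ± 1.5 CPM, SD, n = 3), and that call was lost without control 2, control 3, edited 2 or edited 3 (adjusted p 0.0647, 0.136, 0.0613 and 0.0741) and with DESeq2 (0.0613). Of 19 antigen presentation genes and 10 tested genes of inflammatory cytokines and the inflammasome 0 passed in edgeR's test, but 1 inflammatory gene was called higher with upper-quartile scaling, either other filter, voom or the length trend removed, and without control 2 or edited 2. The adjusted p of these 3 lists was 0.922, 0.707 and 0.922, and adjusted p = 0.969, adjusted p = 0.954 and adjusted p = 0.969 with an estimated correlation. Among 25 genes of endoplasmic reticulum and integrated stress, 2 rose, the serine synthesis genes Psat1 (log2 0.70, SE 0.10) and Phgdh (0.78, SE 0.14), and 4 fell, including Atf3 (-1.37, SE 0.21) and the chaperone Hspa5 (-0.28, SE 0.05; list adjusted p = 0.134). The falls were 2 without control 2, 2 without control 3, 7 without edited 2 and 1 without edited 3, and 0 with controls 1 and 3 left out or with Myl7 as a covariate in edgeR. Of 16 factors of nonsense-mediated decay, Smg1 was the 1 call (log2 -0.19, SE 0.05), past the threshold with all 6 libraries and lost without any 1 of them (adjusted p 0.057 to 0.153) and with upper-quartile scaling (0.0733; list 0.842). Of 24 immediate early genes 1 rose and 2 fell, Atf3 among them (list adjusted p 0.389), with 1 and 4 without control 2, 4 and 4 without edited 2, and 0 and 1 without control 1, control 3 or edited 3. In the clock output list 1 of 19 genes fell, Hlf (48.3 ± 3.5 to 35.6 ± 2.0 CPM; list 0.675), and among 16 heat shock genes 1 fell, Hspe1 (log2 -0.25, SE 0.06; list 0.389), a call lost without control 1, control 3 or edited 3 (adjusted p 0.121, 0.083 and 0.0815).

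Markers of other heart tissues differed between libraries. Unscaled CPM of the atrial myosin light chain Myl7 were 6.74, 323 and 0.20 in controls 1, 2 and 3, and 550, 378 and 948 in edited 1, 2 and 3. Those of the atrial peptide gene Nppa were 24.3, 1075 and 14.9 against 863, 526 and 1144. Both genes were uncalled in edgeR (adjusted p 0.556 and 0.783), and both passed with voom (0.00556 and 0.015), Nppa also without control 2 (0.0339). Of 10 tested atrial markers 2 rose, Tbx18 (log2 0.49, SE 0.09) and Nr2f2 (0.35, SE 0.08), the latter not without control 1 (adjusted p 0.0664), control 3 (0.119) or edited 3 (0.101); 5 were called without control 2, 7 with voom and 1 without control 1 or control 3. The list's adjusted p was 0.00144, and with an estimated correlation adjusted p = 0.462. Eln, the elastin of large vessel walls, was at 539, 728 and 534 unscaled CPM in controls and at 1977, 7814 and 2655 in edited hearts (adjusted p 0.0975, and 0.0365 without edited 2, 0.00133 by DESeq2 and 8.71e-04 by voom). Of 10 mesothelial markers 8 rose and 1 fell, among them Msln (2.63 ± 0.17 to 9.88 ± 2.9 CPM), Upk1b (0.29 ± 0.08 to 1.68 ± 0.63) and Krt19 (1.2 ± 0.21 to 3.13 ± 0.95; SD, n = 3); the list's adjusted p was 1.69e-11, and with an estimated correlation adjusted p = 0.204. With controls 1 and 3 left out 0 atrial and 0 mesothelial markers passed in edgeR. The atrial list was then not past the threshold (median 0.17, adjusted p 0.307), nor with Myl7 as a covariate (-0.01, 0.459), while the mesothelial list passed in both (medians 1.61 and 2.42, adjusted p 6.12e-07, from 1 control library, and 2.4e-17), with 4 members called with the covariate and 5 without control 3. Xist, expressed from the inactive X chromosome of females, had 9601 counts in control 1 and at most 21 in any other library, while 4 Y-linked genes together had 0 counts in control 1 and 3397 to 4588 in the others.

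**Figure D2:**
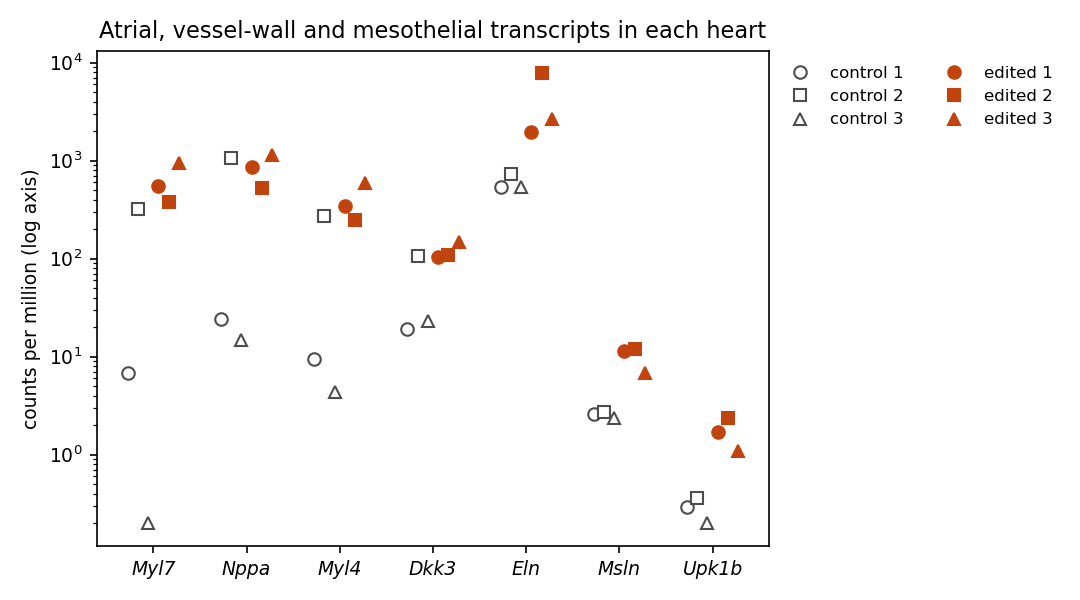
Unscaled CPM, on a log axis, of 4 atrial genes, the elastin gene Eln and 2 mesothelial genes in each library. Open grey symbols are controls and filled symbols edited hearts. Myl7 spans 0.20 to 948 CPM; control 2 lies near the edited hearts for the atrial genes and near the other controls for Eln, Msln and Upk1b.

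Other cell types changed less. Of 20 macrophage markers 0 passed in edgeR, and the list was lower by camera (median log2 -0.17, adjusted p 0.0336), a call lost without control 2 (0.123), edited 1 (0.0776) or edited 2 (0.0909) and with voom (0.0997). Of 18 endothelial markers 1 fell, Aqp1 (log2 -0.46, SE 0.07; list adjusted p 0.0361), and the list's call was lost without control 1 (0.0944), edited 1 (0.182) or edited 3 (0.0579), with upper-quartile scaling (0.0509), with the length trend removed (0.0953), with controls 1 and 3 left out (0.222) and with Myl7 as a covariate (0.478). Of 8 Schwann and nerve markers 1 rose (list adjusted p 0.00754), and the list was not past the threshold with controls 1 and 3 left out (0.615), with Myl7 as a covariate (0.986) or with the length trend removed (0.0728). Of these markers 4 were called without control 2, 3 without edited 2 and 5 with voom, and 0 without control 1, control 3, edited 1 or edited 3 in edgeR. Of 6 tested adipocyte markers 2 fell, Pnpla3 (log2 -1.18, SE 0.13) and Slc36a2 (-0.46, SE 0.09). The adipocyte list was called lower (adjusted p 0.0269) although its median was 0 and its mean log2 0.30, since the brown fat gene Ucp1 stood at 28.2 CPM in edited 2 and at most 2.69 elsewhere. That call was lost without control 1 (adjusted p 0.0621), control 2 (0.0538), edited 1 (0.140) or edited 3 (0.0657), without a filter (0.274), with voom (0.110), with the length trend removed (0.0911), with controls 1 and 3 left out (0.063) and with Myl7 as a covariate (0.532). With an estimated correlation the 4 lists had adjusted p = 0.344, adjusted p = 0.475, adjusted p = 0.459 and adjusted p = 0.420. Fibroblast, smooth muscle and pericyte, B cell, erythroid, skeletal muscle and sex-linked lists were not past the threshold (adjusted p 0.173, 0.263, 0.957, 0.833, 0.753 and 0.737). The fibroblast list passed upward without control 2 (0.0263) or edited 1 (0.00998) and with voom (0.0301), the smooth muscle list without edited 3 (0.00417) and with Myl7 as a covariate (9.4e-07). The skeletal muscle list passed downward with the length trend removed (0.0394), and the sex-linked list without control 1 (0.0221) and with controls 1 and 3 left out (0.0119). T and NK cell, neutrophil, thymus and lung lists had too few tested members, with 0 calls among 3, 3, 3 and 1. In all, 17 of 33 lists passed, 7 upward and 10 downward, with 0 passing at an estimated correlation and 6 by fry. By fry the hypertrophy, sarcomere, p53, calcium handling, mitochondrially encoded and fatty acid oxidation lists passed (adjusted p 0.00484, 0.00807, 0.00989, 0.0175, 0.026 and 0.0272). The cell cycle, mesothelial, oxidative phosphorylation and matrix lists did not (fry adjusted p 0.0507, 0.0507, 0.0597 and 0.109). The preset correlation also passed between 4 and 13 lists in every other split of the 6 libraries, although those splits called 0 genes. A pass at that correlation alone is therefore weak evidence of a difference between the groups.

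**Figure D3:**
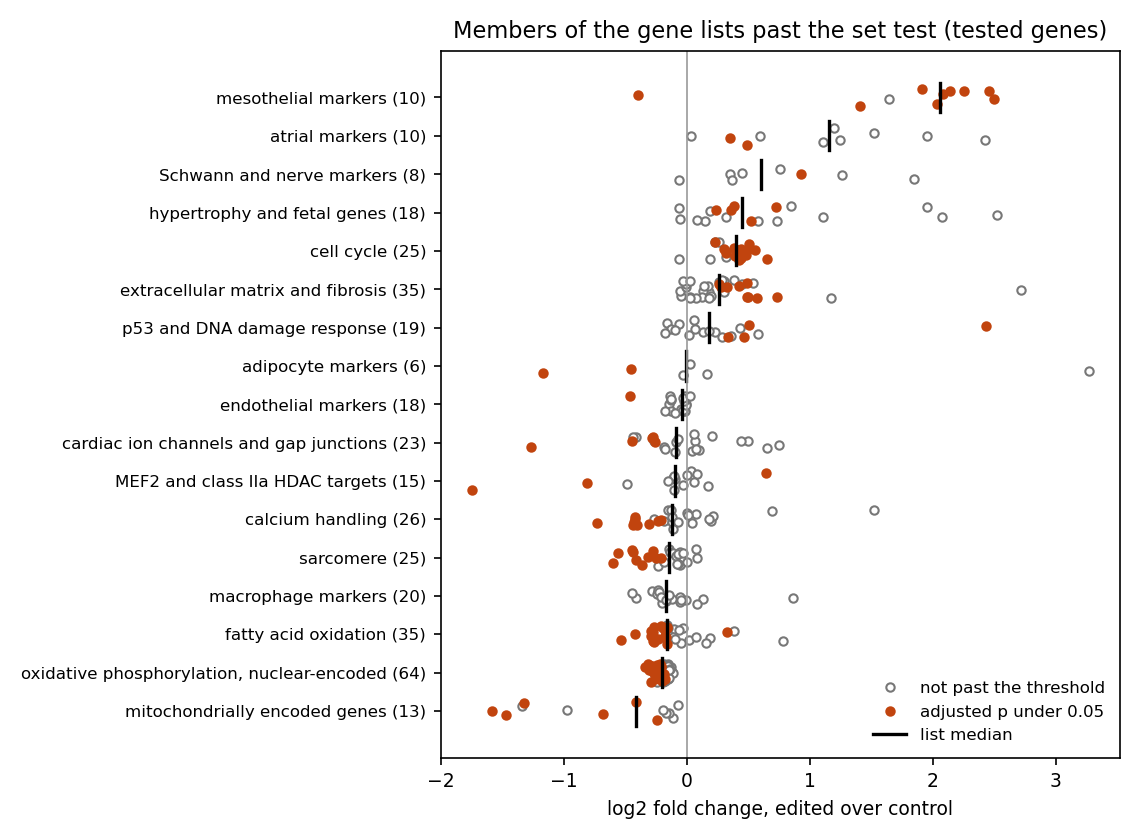
Log2 fold change, edited over control, of each tested member of the 17 lists past camera's threshold with the preset correlation. Filled points passed the gene test, open points did not, vertical bars are list medians, and the number of tested genes stands in brackets. Nuclear-encoded oxidative phosphorylation genes lie close to their median of -0.21, and mesothelial markers reach a median of 2.06.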

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

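Alternatives that left out controls 1 and 3, used Myl7 as a covariate, removed the length trend or left out pseudogenes were chosen after the data were seen. Camk2d kept its direction in every alternative (log2 -0.84 to -0.57) and its call in all but 1: with controls 1 and 3 left out it was -0.60, where only 1 control library remains. The genes changed (1438, with 733 genes higher in edited hearts, 705 genes lower in edited hearts and 43 genes changed by at least 1.5-fold) became 2239 and 1290 higher, with 192 above 1.5-fold, without a filter; 2285, 1194 and 1091 with voom; 169, 77, 92 and 11 with controls 1 and 3 left out; and 121, 65, 56 and 11 with Myl7 as a covariate. They were 503 at an adjusted p under 0.01 and 2222 under 0.10. Leaving out 1 library gave 446 (without control 3) to 1553 calls, 221 to 827 higher, 225 to 753 lower and 18 to 70 above 1.5-fold. Beyond the fewer samples, the cause was not tested. All 1438 genes kept their direction in the fits that tested them. That was likely in advance, as these fits reuse the libraries that gave the calls. With the covariate 108 kept their call. The 17 lists became 0 with an estimated correlation. Same-numbered libraries did not deviate together (correlations 0.02, -0.10 and -0.08), and not every library correlated best with its own number. These correlations gave no sign of pairing by number, but with 3 libraries per group they cannot exclude it. The replicate block gave 1077 calls, 620 higher and 457 lower, 80 above 1.5-fold and 14 lists. It ended the macrophage, endothelial and adipocyte list calls (camera adjusted p 0.0533, 0.0559 and 0.656). The sex-linked list turned downward without control 1, the female library (median -0.22; range -0.22 to 0.83 over single libraries left out), and with controls 1 and 3 left out (-0.33). The Schwann list shrank to no difference with the covariate (median 0.09, adjusted p 0.986). DESeq2 gave no list test. Depth limits genes near 1 CPM, where a library holds about 20 reads.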

Other observations

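The tests in this part were chosen after the results were seen, except the heterogeneity of the sarcomere list, the matched gene lists, the receptor genes and the split by identity, whose bounds were set before its result but after the fall of the pseudogenes was known. Further genes passed the test for a change above 1.5-fold and were picked here after their values were seen. Adamts8, a secreted protease, rose from 7.35 ± 2.6 to 39.2 ± 4.2 CPM, Ptgds, a prostaglandin D synthase, from 18.9 ± 3.0 to 50.3 ± 3.4, and Prss23 from 14.2 ± 1.9 to 30.7 ± 3.8. Klhl33 fell from 15.2 ± 2.4 to 6.29 ± 0.58 CPM and the phospholipase gene Pla2g5 from 32.3 ± 4.0 to 14.6 ± 2.3 (SD, n = 3).

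The real split of the 6 libraries gave 1438 changed genes, 43 changes above 1.5-fold and 17 lists, against at most 0, 0 and 13 in the other splits. Each of the other splits passed at least 4 lists. Only 1 of the 10 splits, the real one, gave as much in each case, and 10 splits are too few for a share under 0.05.

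The atrial transcripts Myl7, Nppa and Myl4 were abundant in the edited hearts and control 2 and scarce in controls 1 and 3. The called markers Tbx18 and Nr2f2 did not follow this, as control 2 lay near the other controls. Unscaled CPM in controls 1, 2 and 3 were 11.55, 11.43 and 11.29 for Tbx18, and 25.55, 27.62 and 23.2 for Nr2f2. Different amounts of atrial tissue in the collected hearts and a response to the base editor or the edit cannot be told apart for the part beyond control 2, since that untreated heart reached 51.6% of the edited mean of Myl7 and the other controls almost none. Ratios of Myl4 and Nppa to Myl7 decide nothing, as they spanned up to 2.76-fold in the 4 libraries that hold these transcripts, where Myl7 itself spanned 2.94-fold. Different sides of the atria in control 2 and in the edited hearts are a candidate explanation for Bmp10, which is expressed in the right atrium: it had 1933 counts in control 2 and at most 2 in an edited heart, so that Bmp10 per Myl7 in edited hearts was at most 0.04% of that in control 2. A fall of Bmp10 by the treatment stays open.

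In edited hearts 9 of 26 calcium handling, 10 of 25 sarcomere, 34 of 64 oxidative phosphorylation and 18 of 35 fatty acid oxidation genes were lower, and none of these lists passed at an estimated correlation (adjusted p 0.204, 0.167, 0.454 and 0.344). Atrial tissue as the whole cause is argued against for the calcium handling and sarcomere lists, whose medians kept at least 113.5% of their size with Myl7 as a covariate (87.9% and 77% with controls 1 and 3 left out), and for fatty acid oxidation, which kept 92.1%, and 65.3% with controls 1 and 3 left out (with the covariate median -0.15, quartiles -0.20 and -0.02, against -0.17, -0.25 and -0.06), although calls fell from 9 to 4, from 10 to 1 and from 18 to 0 as the median SE of the members rose from 0.065, 0.056 and 0.056 to 0.098, 0.083 and 0.087. For oxidative phosphorylation atrial tissue cannot be told apart from the treatment, as 57.7% of the median stayed and calls fell from 34 to 0. Loss of short transcripts alone is argued against for oxidative phosphorylation, where 75.7% of the median and 27 of 34 calls stayed with the length trend removed. Dilution alone, by tissue without sarcomere transcripts, would lower sarcomere genes alike, yet their Cochran Q per degree of freedom was 10.03. Dilution as a part of the fall stays open, as does dilution by tissue that holds some of these transcripts. Q only asks whether all members share a common shift. An effect of Camk2d loss, of the virus or of the editor stays open, untested, as does a difference in collection or preparation between the groups.

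Processed pseudogenes were lower in edited hearts (19 of 69 fell and 0 rose, median log2 -0.54), as were ATP6, COX3 and COX2. Reads shared between near-identical copies may be counted differently in the 2 groups: of 67 pseudogenes paired with the coding gene they match best, the 34 with at least the median identity of 99.2% had a median log2 of -0.73, against -0.34 in the 33 others (difference -0.40, permutation p 4e-04). The 6 mitochondrial genes covered over 50% by a nuclear transcript at 98% identity or more had a median log2 of -1.34, against -0.17 in the other 7, with ND6 (0% covered, log2 -0.68) and ND4 (63.6% covered, log2 -0.25) as exceptions. Loss of short transcripts is argued against, as 95% of 10000 lists of coding genes matched on length and expression had medians between -0.02 and 0.16. How closely the matched genes agreed in length was not checked, so a length effect is not excluded. Genomic DNA reads are argued against, since olfactory and vomeronasal receptor genes in controls reached 5.64% of the pseudogenes' fall per kb. What differed between the groups' reads was not tested, and no biological explanation was tested.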
